A study of Mus musculus with 44 samples.

How the data were processed

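RNA of single cells was measured in organoids from the small intestine of a mouse line in which 1 allele of Lgr5 carries a GFP and diphtheria toxin receptor knock-in. Per the labels, the organoids were first kept with the GSK3 inhibitor CHIR99021 and valproic acid and then treated with 100 ng/mL RANKL, alone or with 40 µM CSRM617; viable cells were sorted by light scatter into 384-well plates and libraries were made with a modified CEL-Seq2 protocol, which counts the 3' ends of transcripts with UMIs. The deposited count tables hold UMI counts per gene and well, whole numbers that the authors had not normalized. The submitters' processing notes name kallisto and bustools, Seurat 3.1.5 and the GRCm38 genome build; kallisto and bustools versions are not given in the sources used here. The authors also deposited natural log tables, whose values were checked to equal the natural log of 1 plus the count scaled to 10000 per well within a tolerance of 1e-9, so that these tables add nothing to the counts and were not tested. The RANKL table had 21099 genes and 6636 wells, and the RANKL+CSRM617 table had 9257 genes, 7 of them without a count, and 1903 wells. The poorest deposited wells had 657 and 344 UMIs, so the tables had been filtered before deposit. Neither table held genes encoded in mitochondria or spike-in rows, so that neither could serve as a quality measure and a repeat without mitochondrial genes was not run. Gene symbols were matched to GENCODE M21 on GRCm38, with 20545 and 9146 symbols found there; coordinates come from that annotation and no exon-level values were used.

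Wells with 1000 or more UMIs were kept, 6558 and 1673, and a plate needed at least 20 kept cells, which all 44 plates had. No doublet caller was run, because each well was sorted as a single cell; 9 and 10 kept cells (0.137% and 0.598%) had over 3 times the median UMIs of their plate. UMIs are single molecules, so intervals and floors cover counting error only. The most abundant gene model, an unnamed clone-derived model, took 10.8% of UMIs in the RANKL table and 14.4% in the other, and the counts of called genes were repeated without it. Arms were compared over the 9230 genes in both tables, which hold 96.9% of the RANKL UMIs.

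For each plate, counts were summed over its cells. The sums were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood test, filterByExpr, all days of the arm, or all shared days of both arms, in a single fit) with Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. The SE of a log2 fold change is its size over the square root of the F statistic. CPM are scaled by the TMM library size, within an arm for changes by day and over both arms for comparisons of arms. Gene lists of cell types and pathways, fixed with the design, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with the correlation estimated from the data. Over the 8 comparisons, 91 list tests passed and 41 did so with the estimated correlation; beside each list the text gives that p where the call was lost.

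Cells were clustered within each table on 2000 variable genes, 30 principal components and 15 neighbours (Leiden, leidenalg 0.10.2 and igraph 0.11.9, resolution 1.0). A cluster was named for a class when at least 3 of its fixed markers were among its 50 genes of highest fold and its leading genes did not go against the name; other clusters stayed unnamed, which gave 15 and 11 clusters. Names rest on these rebuilt clusters and can differ from the study's own. Shares per plate were related to the day by permutation tests with 100000 resamples (scipy 1.17.1), exact where fewer than 10 values entered, and between arms by an exact permutation of plates within days; all tests were two-sided. A share of 0 is given with the limit that 3 counts set, a 95% limit, where the table had a cluster of that class. Folds against a group without counts are lower bounds against 3 counts over the group, and where the lower group had 1 to 3 counts, or a day within days 4 to 6 had none, the ratio of the summed counts and its 95% counting interval are given.

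Genes were named by a rule. In each comparison it took, among genes past the test with a mean log2 CPM of 5 or more and no overlap between the plates compared, the 10 largest rises and 10 largest falls, or 5 and 5 for day 3 and day 0. For the comparison of changes the overlap was not required. It added up to 4 called members of each list with the largest change, and 16 genes of prior interest, such as Onecut2, Tnfrsf11a, Spib, Lgr5, Olfm4 and Alpi; the text gives a selection of these. Slc12a2, Apoa1 and Ier3 on day 3 of RANKL, Ephb2 on days 6 and 9, Areg on day 6, and Dpp4 on day 3 of RANKL+CSRM617 fall outside the rule and were chosen after their values were seen, to name the members of small counts. Groups, comparisons, tests, lists, markers, this rule and most alternatives were set before the data were examined. The alternatives without the most abundant gene, with plates of 50 or more cells only, with the plate tag as a factor, with crossed replicate numbers and with clustering on non-marker genes were chosen after seeing the data.

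The test was tried on simulated counts drawn from the real plates' means with 200 genes changed. A log2 fold change of 1 was recovered for 59.8% of changed genes on day 3 of RANKL (9711 genes), 59.6% on day 6 (9747 genes) and 57.7% on day 9 (9702 genes), but for 21.9% on day 3 (6178 genes) and 17.9% on day 6 (6110 genes) of RANKL+CSRM617. A change of 2 was recovered for 96.0%, 91.0%, 87.6%, 75.8% and 68.8% in the same order. Between arms, a change of 1 was recovered for 48.0% over days 4 to 6 (8551 genes), 40.8% at day 0 (8554 genes) and 19.6% for the comparison of changes (8555 genes), where 11.6% of calls were false. Recovery was thus lower in the arm with fewer plates and UMIs. The planned tests within enterocyte-like cells, of RANKL day 6 against day 0 and of the arms over days 4 to 6, were not run, because no plate of RANKL day 6 or of RANKL+CSRM617 days 4 to 6 had 10 such cells.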

Results

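Organoids grown from mouse small intestine were treated with RANKL, the TNF family cytokine that induces M cells, the antigen-sampling cells of the epithelium over lymphoid follicles. A parallel series received RANKL with CSRM617, a small-molecule inhibitor of the transcription factor ONECUT2. Single cells were sorted into 384-well plates and their RNA was counted with molecular identifiers (UMIs). The RANKL arm held 30 plates, 3 for each day from 0 to 9, and the RANKL+CSRM617 arm held 14 plates, 2 for each day from 0 to 6. After the filter on UMIs, 6558 RANKL cells and 1673 RANKL+CSRM617 cells remained, 26 to 282 and 24 to 223 per plate. UMIs per plate ran from 155940 to 1640523 and from 47976 to 835772, and the median per cell from 2968 to 6960 and from 1800 to 3685. The plate was the replicate in every test, so n was 3 per RANKL day and 2 per RANKL+CSRM617 day. Plates of the same day differed by more than the counting noise of UMIs in all 37 pairs, with a chi-square per gene of 2.43 to 27.2. Plates that drew different cells from a single pool can exceed that noise too, so the value does not show a difference beyond the draw of cells. The labels do not say that plates came from separate cultures, so p-values measure the spread between plates, which may be technical. No untreated plates of later days were analysed here, and each change from day 0 therefore joins RANKL with time in culture. The organoids were first kept with CHIR99021 and valproic acid, so any change of that medium at the start of RANKL is joined as well.

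The first question was whether the target of the inhibitor and the receptor of the cytokine were expressed as the organoids responded. Onecut2 (chromosome 18, 64340020 to 64400987, GRCm38), the gene of the inhibited factor, peaked on day 3 in both arms. In the RANKL arm its level rose from 374 ± 102 normalised CPM (TMM-scaled counts; SD, n = 3) on day 0 to 1236 ± 134 on day 3 and was 584 ± 36.5 on day 6. In the RANKL+CSRM617 arm it rose from 400 ± 17 to 1462 ± 24.7 (SD, n = 2) on day 3 and was 879 ± 59.6 on day 6. The log2 fold change on day 3 was 1.66 ± 0.15 (SE, edgeR adjusted p = 1.27e-10) with RANKL and 1.87 ± 0.22 (adjusted p = 1.26e-06) with RANKL+CSRM617. CSRM617 acts on the protein, so the RNA level does not measure inhibition. Tnfrsf11a (chromosome 1, 105780718 to 105847981), which encodes RANK, the receptor of RANKL, rose from 47.2 ± 9.95 to 247 ± 33.1 CPM on day 3 in the RANKL arm and from 53.3 ± 20.4 to 265 ± 48.6 CPM with the inhibitor.

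**Figure D1:**
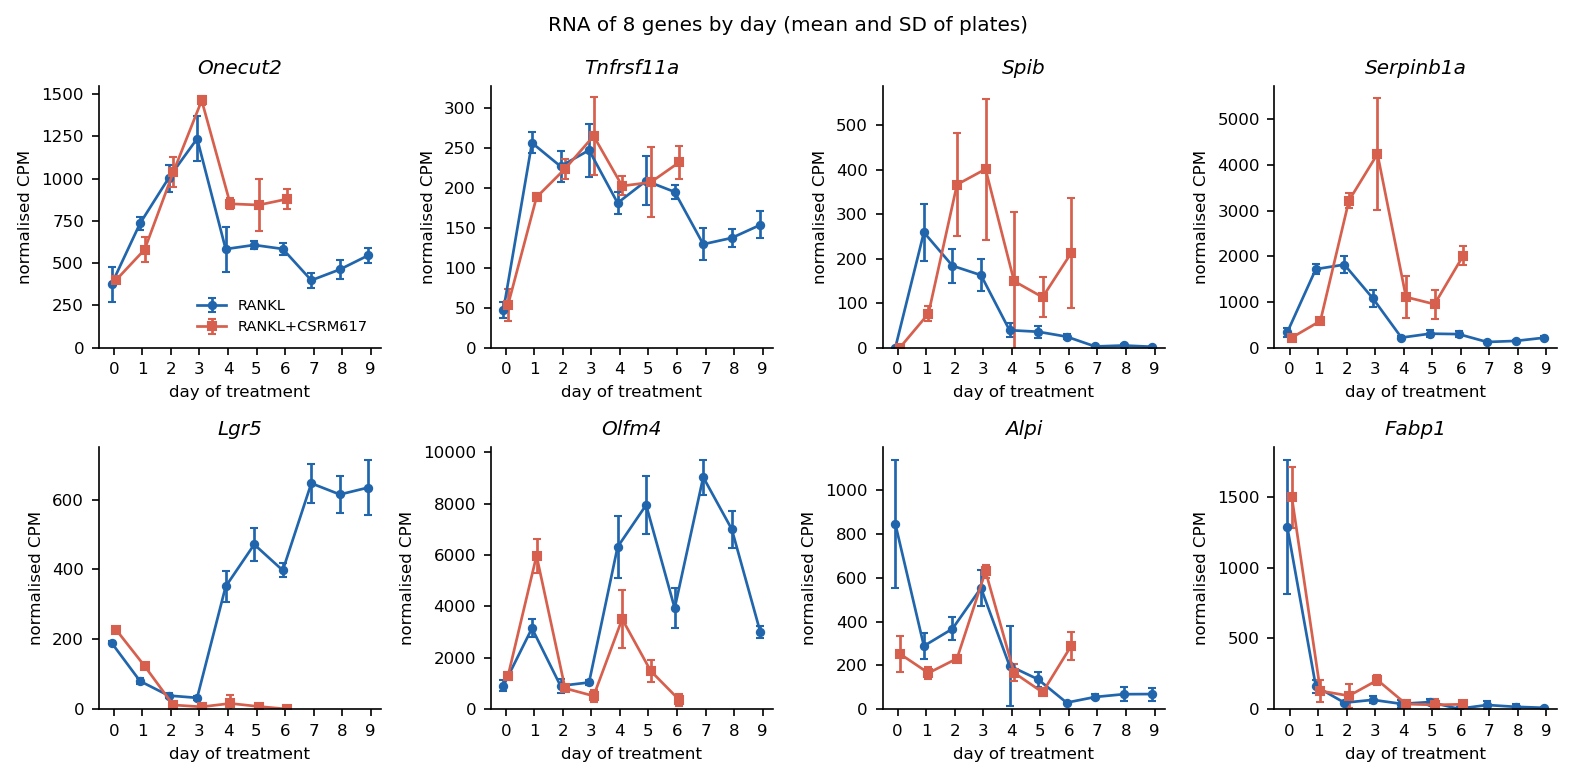
Normalised CPM of 8 genes by day of treatment, as the mean and SD of 3 RANKL plates or 2 RANKL+CSRM617 plates per day, with error bars drawn no lower than 0. Onecut2 was highest on day 3 in both arms, and Lgr5 stayed at or under 16.2 CPM from day 2 to day 6 in the RANKL+CSRM617 arm while it reached 472 CPM on day 5 with RANKL.

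Cell classes were followed over time in the RANKL arm by clustering and markers fixed in advance. M cell-like cells formed a cluster of 583 cells led by Id3, Spib, Id1 and Serpinb1a and another of 330 led by Serpinb1a, Clec2h and Spib. The larger was named on 3 fixed markers. M cell-like cells were not seen on day 0 (0 of 481 cells, which allows a share of up to 0.624%). Their share of a plate was 24.5% ± 2.86 on day 1, 45.7% ± 2.08 on day 2 and 44.6% ± 3.83 on day 3 (SD, n = 3). They made up 9.14% ± 0.244 on day 4 and 1.81% on day 6. Enterocyte-like cells, the absorptive class, went from 45.7% ± 6.90 on day 0 to 10.0% on day 1 and 9.17% on day 2. They were 24.2% ± 1.47 on day 3 and 1.28% ± 0.536 on day 6. This class was held by different clusters, with 233 of its 234 day 0 cells in a cluster led by Fabp1 and Gstm3 and 192 of its 196 day 3 cells in another led by Reg3b and Apoa4. Stem-like cells, led by Olfm4, Lgr5 and Rgcc, were at or under 2.31% to day 3, then 25.8% ± 2.92 on day 4 and 46.4% ± 1.73 on day 7. Unnamed cells were 48.1% of a day 0 plate and had Lgr5 at 301.8 ± 19.5 CPM (SD, n = 3). Lgr5 was at 48.1 ± 14.7 CPM in enterocyte-like cells of day 0 and 714.7 ± 146 in stem-like cells of days 4 to 9. The low stem-like share of day 0 may thus depend on the naming rule. Cycling-like cells went from 0.442% on day 0 to 27.9% on day 1. A cluster led by Rrm2, Uhrf1, Clspn and Mcm3, genes of DNA replication, stayed unnamed and held 26.3% of day 1 cells. Unnamed clusters with Rrm2 and Uhrf1 among their leading genes also held 17.2% of RANKL day 5 cells and 19.3% of RANKL+CSRM617 day 1 cells. The cycling-like share is therefore not that of all cycling cells. Over all 30 plates, 5 of 7 classes followed the day (permutation test, Benjamini-Hochberg adjusted over 7 classes). Single plates were permuted here and within spans of days, although plates of a day share its state. A small p therefore shows that days differed by more than their plates did, and does not measure how steady a trend was. The stem-like share rose, with Pearson r = 0.812 (p = 1e-05, the smallest these permutations give; adjusted p = 3.5e-05) and Spearman rho = 0.742 (adjusted p = 7e-05). Without the first 2 plates of day 0 r was 0.791. All plates of days 0 and 9 are equally far from the median day, and row order chose these 2. Values below without 2 plates, or without the 2 farthest, likewise leave out the first 2 plates of the first day of their span. The enterocyte-like share fell (r = -0.700, adjusted p = 3.5e-05; rho = -0.760, adjusted p = 7e-05; r = -0.621 without the 2 farthest plates). By Pearson's r alone it rose within days 1 to 3 (r = 0.825, exact permutation test adjusted over 19 relations, adjusted p = 0.0352; rho = 0.738, adjusted p = 0.0876; r = 0.890 without 2 plates) and fell within days 4 to 9 (permutation test, r = -0.643, adjusted p = 0.0163; rho = -0.492, adjusted p = 0.0885; r = -0.504 without 2 plates). Enteroendocrine-like cells, which secrete hormones, rose (r = 0.674, adjusted p = 9.33e-05; rho = 0.669, adjusted p = 0.00014; r = 0.675 without 2 plates), as did goblet- and Paneth-like cells, the secretory class (r = 0.526, adjusted p = 0.0048; rho = 0.506, adjusted p = 0.00886; r = 0.613 without 2 plates). Within days 1 to 3 the goblet- and Paneth-like share fell, by Pearson's r alone, from 5.03% to 1.97% (exact permutation test, r = -0.786, adjusted p = 0.0352; rho = -0.791, adjusted p = 0.0582; r = -0.603 without 2 plates), and within days 4 to 9 it had no tested trend (permutation test, r = 0.438, adjusted p = 0.109; rho = 0.448, adjusted p = 0.104; r = 0.253 without 2 plates). The M cell-like share fell over the whole course (r = -0.520, adjusted p = 0.0048; rho = -0.457, adjusted p = 0.0162; r = -0.676 without 2 plates). It rose within days 1 to 3 by Pearson's r alone (r = 0.817, exact permutation test adjusted over 19 relations, adjusted p = 0.0352; rho = 0.685, adjusted p = 0.104; r = 0.67 without 2 plates), and fell within days 4 to 9 by both measures (permutation test, r = -0.780, p = 1e-05, the smallest possible here, adjusted p = 0.00019; rho = -0.814, adjusted p = 0.00152; r = -0.700 without 2 plates). The stem-like share fell within days 1 to 3, from 2.31% to 0.123% (exact permutation test, r = -0.883, adjusted p = 0.0189; rho = -0.858, adjusted p = 0.0264; r = -0.818 without 2 plates), as did the cycling-like share, from 27.9% to 13.9% (r = -0.902, adjusted p = 0.0123; rho = -0.896, adjusted p = 0.0170; r = -0.847 without 2 plates). Within days 4 to 9 the stem-like share had no tested trend (permutation test, r = 0.261, adjusted p = 0.400; rho = 0.216, adjusted p = 0.498; r = 0.18 without 2 plates), so its rise with the day rests on the step between days 3 and 4.

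**Figure D2:**
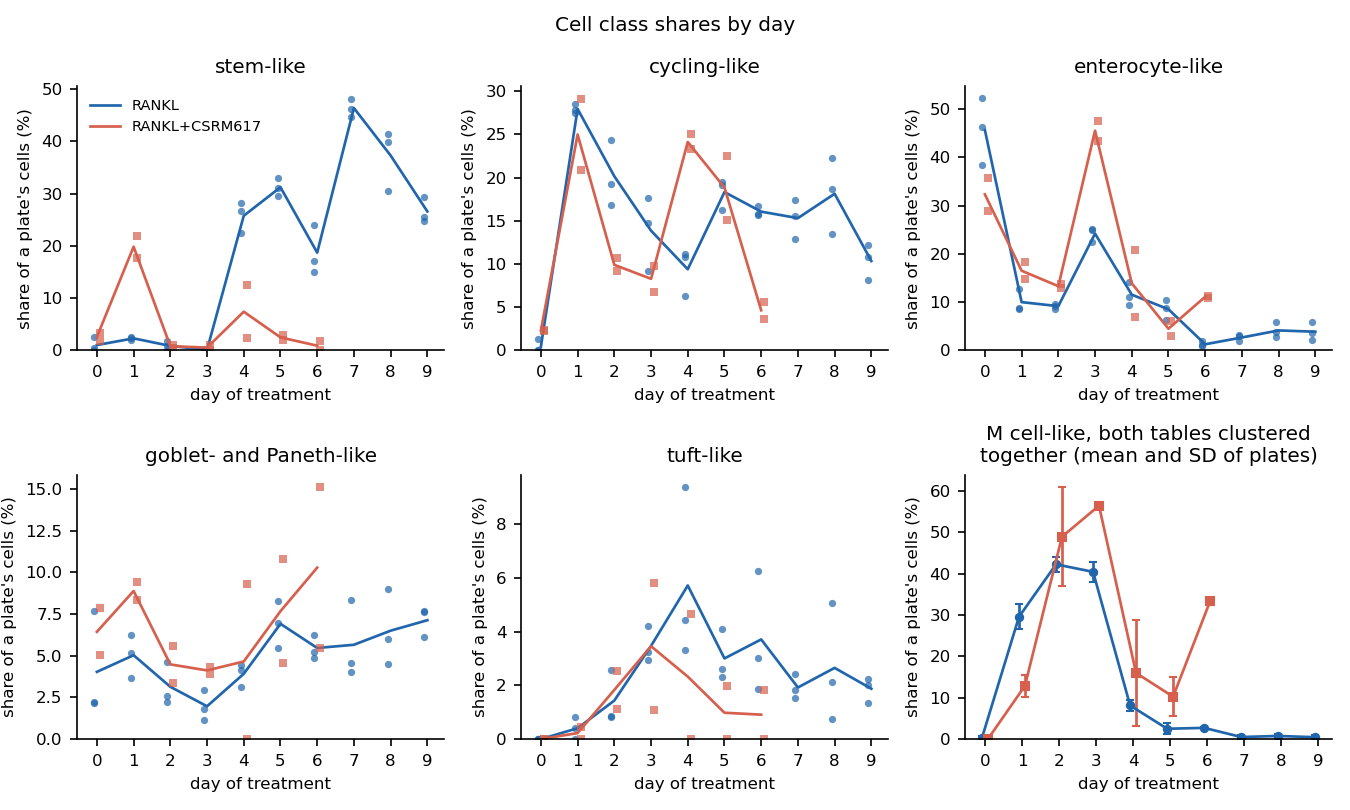
Share of a plate's cells by day for 5 cell classes, with plates as points and day means as lines. M cell-like cells are shown with both tables clustered together, without correction for differences between them, as mean and SD of plates. Stem-like cells reached 46.4% on day 7 with RANKL, and over days 4 to 6 averaged 25.2% with RANKL and 3.61% with RANKL+CSRM617.

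On day 3 of RANKL, genes of M cells and of the NF-kappaB response rose, and genes of the interferon response fell. All 7 tested members of the M cell list rose (camera adjusted p = 5.91e-15). The list fixed with the design holds further markers that were not tested, so this covers a part of it. Ccl9, a chemokine of the follicle-associated epithelium, went from 1.55 ± 1.41 to 178 ± 24.9 CPM. Anxa5, a calcium-dependent phospholipid-binding protein, went from 27.6 ± 7.42 to 818 ± 103 CPM. Spib, the Ets family factor that M cell differentiation needs (chromosome 7, 44525993 to 44532071), had no count on day 0 and 674 UMIs on day 3, at least 131-fold higher against a floor of 3 counts over the group. Of the 15 NF-kappaB response genes, 13 rose (adjusted p = 2.3e-17), with log2 fold changes of 4.19 ± 0.30 for Ccl20, a chemokine that attracts CCR6-positive cells, and 4.12 ± 0.27 for Tnfaip3, an inhibitor of the same pathway. Of 7 BMP target genes, 6 rose (adjusted p = 3.09e-05), including Id2, a helix-loop-helix inhibitor of differentiation factors, at 3.22 ± 0.16. All 14 interferon response genes fell (adjusted p = 1.03e-16), for example Oasl2, an antiviral oligoadenylate synthetase-like gene, from 219 ± 34.5 to 15.2 ± 3.67 CPM.

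In all, 2043 of 10000 tested genes changed on day 3 of RANKL at an adjusted p of 0.05, 1023 up and 1020 down. With each cell weighted equally, 68.7% of the calls were rises. Other large rises were those of Adgrd1, an adhesion G protein-coupled receptor, and H2-M2, a nonclassical MHC class I gene, at least 173-fold and 163-fold. Ubd, a ubiquitin-like gene induced by TNF, and Serpina1b, a member of the antitrypsin family, rose at least 110-fold and 54.4-fold. Large falls besides those of interferon genes included Hsd17b13, a lipid droplet protein (-4.36 ± 0.33), Fabp1, a fatty acid binding protein of enterocytes (-4.35 ± 0.41), and Rgcc, a cell cycle regulator (-4.16 ± 0.30). Lgr5, the R-spondin receptor that marks crypt stem cells (chromosome 10, 115450311 to 115587780), fell from 190 ± 4.04 to 32.2 ± 5.58 CPM (log2 fold change -2.56 ± 0.16, adjusted p = 2.92e-14). In this organoid line 1 Lgr5 allele carries a reporter knock-in. Olfm4, another stem cell gene, was at 0.21 ± 0.18 (adjusted p = 0.469), and of the 8 stem genes Ascl2 and Slc12a2 rose while Lgr5, Smoc2 and Rgmb fell (camera adjusted p = 0.15). ER stress genes fell in 10 of 12 members (11 adjusted over the list alone, adjusted p = 2.22e-06), and immediate early genes in 7 of 11 (adjusted p = 3.74e-05), Fos by 3.15 ± 0.25. Junb and Ier3, also immediate early, rose. Both calls were lost without the first day 0 plate (adjusted p = 0.162 and 0.106). That of Junb was lost too without the second day 0 plate or the third day 3 plate (0.0787 and 0.114, and 0.00374 to 0.162 over its alternatives), that of Ier3 without the third day 0 plate or the first day 3 plate (0.163 and 0.164; 0.0214 to 0.164). The lists called so far passed also with an estimated correlation. Tuft genes, 5 of 6 of which rose (adjusted p = 0.000789, and adjusted p = 0.142 with an estimated correlation), and enterocyte genes, 6 of 13 of which fell (adjusted p = 0.0216, and adjusted p = 0.532 with an estimated correlation), did not. Apoa1 was the enterocyte gene that rose, a call lost without the first or the third day 0 plate (adjusted p = 0.0547 and 0.0511, and 2.18e-14 to 0.0806 over its alternatives). Unless another count is given, the number of list members adjusted over the list alone was the same. Plates did not overlap for 32.2% of tested genes, where chance gives 10% with 3 plates against 3.

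By day 6 of RANKL, stem cell genes and Wnt targets were higher than on day 0 and the enterocyte program was lower. Of 8 stem genes, 7 rose (camera adjusted p = 7.6e-05; median log2 fold change 0.97). Among them, Lgr5 went from 190 ± 4.04 to 398 ± 20.1 CPM, Olfm4 from 913 ± 206 to 3932 ± 770 CPM and Slc12a2, a chloride cotransporter of crypt cells, from 1396 ± 157 to 4240 ± 526 CPM. Of 13 Wnt targets, 9 rose and Ephb2, a receptor kinase of crypt cells, fell (adjusted p = 0.000268), with Sox9, a crypt transcription factor, at 1.33 ± 0.14 and Cd44, a hyaluronan receptor, at 1.29 ± 0.14. All 13 enterocyte genes fell (adjusted p = 3.37e-09, and adjusted p = 0.0545 with an estimated correlation), including Alpi, the brush border alkaline phosphatase, from 846 ± 294 to 29.4 ± 5.13 CPM. All 14 lipid absorption genes fell as well (adjusted p = 5.88e-09), with Fabp1 at -9.18 ± 0.64, Fabp2 at -5.63 ± 0.34 and Mttp, which loads lipid onto chylomicrons, at -4.82 ± 0.33. Cholesterol synthesis genes fell in 15 of 17 (17 adjusted over the list alone, adjusted p = 1.68e-12), Insig1, a sterol sensor, from 1151 ± 173 to 140 ± 29.8 CPM.

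On day 6 the test called 3828 genes, 1893 up and 1935 down. With each cell weighted equally, 66.9% of the calls were rises. M cell genes still exceeded day 0 in 5 of 7 members (adjusted p = 7.6e-05), with Anxa5 at 3.00 ± 0.20 and Spib at least 21.6-fold higher, and NF-kappaB genes in 12 of 15 (adjusted p = 7.16e-09). Onecut2 was at 0.57 ± 0.15 (adjusted p = 0.00266) and Tnfrsf11a at 1.96 ± 0.17. Large rises included H2-M2 and Slc17a8, a vesicular glutamate transporter, at least 113-fold and 90.0-fold, and Serpina1b and Ubd, at least 61.5-fold and 50.3-fold. Clu, the secreted chaperone clusterin, rose from 1.27 ± 2.20 to 107 ± 16.6 CPM. Large falls also included Gstm3 and Gsta1, glutathione transferases (-7.26 ± 0.50 and -5.92 ± 0.38), and Hsd17b13 (-7.25 ± 0.47). Gst, Serpina1 and defensin genes have near-identical copies that counting can split, so their single values are uncertain. NRF2 and xenobiotic genes, which include these transferases, fell in 14 of 16 (15 adjusted over the list alone, adjusted p = 9.21e-09), ER stress genes in 11 of 12 (adjusted p = 7.23e-06) and interferon genes in 14 of 14 (adjusted p = 3.77e-11). Carbohydrate absorption genes fell in 12 of 13 (adjusted p = 1.08e-05, and adjusted p = 0.0523 with an estimated correlation). Of 10 genes of the fetal-like regenerative list, 4 rose, Clu and the annexin Anxa3 (3.20 ± 0.41) among them, and Areg, an EGF receptor ligand, fell (adjusted p = 0.0136, and adjusted p = 0.142 with an estimated correlation). The call of Areg was lost with each cell weighted equally (adjusted p = 0.169, and 4.89e-05 to 0.169 over its alternatives). Mki67, a proliferation marker, was at 1.09 ± 0.26. Plates did not overlap for 44.3% of tested genes, where chance gives 10%.

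On day 9 of RANKL, the latest plates, stem genes stayed above day 0 and M cell genes were nearer to it. Of 8 stem genes 7 were higher (camera adjusted p = 2.07e-05; median 1.25), with Lgr5 at 635 ± 78.7 CPM and Olfm4 at 3002 ± 225 CPM, and of 13 Wnt targets 10 were higher (adjusted p = 1.41e-05), Axin2, a feedback inhibitor of the pathway, at 1.26 ± 0.18. Ephb2 was lower, a call lost without the first day 0 plate or the second or the third day 9 plate (adjusted p = 0.0788, 0.101 and 0.123, and 0.00459 to 0.123 over its alternatives). In the M cell list Anxa5, Marcksl1 and Ctsh were higher and 1 of the 7 genes was lower (adjusted p = 0.0195, and adjusted p = 0.16 with an estimated correlation). Spib had 5 UMIs, at least 1.65-fold above day 0. Its test did not pass (adjusted p = 0.109) except with each cell weighted equally (0.000401, and 0.000401 to 0.493 over its alternatives). Serpinb1a, a protease inhibitor, was lower at -0.71 ± 0.19, a call lost without the first day 0 plate (adjusted p = 0.116) or the first day 9 plate (adjusted p = 0.0652, and 5.62e-05 to 0.116 over its alternatives). Ccl9 was at 1.34 ± 0.89 (adjusted p = 0.251), but passed with each cell weighted equally (2.04, adjusted p = 0.000326, and 0.000326 to 0.551 over its alternatives). Enterocyte genes were lower in 12 of 13 (13 adjusted over the list alone, adjusted p = 3.99e-09, and adjusted p = 0.0793 with an estimated correlation), Alpi at -3.64 ± 0.36, Apoa4, an apolipoprotein of chylomicrons, at -3.39 ± 0.71 and Fabp1 at -7.21 ± 0.55.

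Day 9 gave 3638 called genes, 1798 up and 1840 down. With each cell weighted equally, 66.1% were rises. Besides H2-M2 and Slc17a8, at least 41.6-fold and 38.9-fold higher, large rises included Clu, at 128 ± 9.00 CPM (6.11 ± 0.52), Kit, a receptor tyrosine kinase (4.90 ± 0.38), and Clca3a2, a chloride channel regulator (4.21 ± 0.24). Large falls included Fabp1, Ifit1, an interferon-induced antiviral gene (-6.96 ± 0.69), Oasl2 (-5.18 ± 0.31) and Fabp2 (-4.91 ± 0.33). Interferon genes were lower in 14 of 14 (adjusted p = 9.39e-12), cholesterol synthesis genes in 15 of 17 (adjusted p = 2.16e-10), NRF2 genes in 15 of 16 (adjusted p = 1.11e-09) and lipid absorption genes in 13 of 14 (adjusted p = 5.25e-09). Onecut2 was at 0.48 ± 0.15 (adjusted p = 0.0125), a call lost without the second day 0 plate (adjusted p = 0.0722, and 0.000103 to 0.0722 over its alternatives). Called genes by day were 2375, 2148 and 2043 on days 1 to 3, and 2146, 3437, 3828, 3299, 3515 and 3638 on days 4 to 9. Plates did not overlap for 42.8% of tested genes on day 9, where chance gives 10%.

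On day 3 of RANKL+CSRM617, M cell and enterocyte genes were higher and stem genes lower than on day 0. All 7 tested M cell genes rose (camera adjusted p = 1.19e-13; median log2 fold change 4.28). Serpinb1a went from 219 ± 21.6 to 4238 ± 1219 CPM (SD, n = 2), Anxa5 from 20 ± 2.51 to 1705 ± 688 CPM, and Spib rose at least 136-fold. Of 12 NF-kappaB genes 9 rose (11 adjusted over the list alone, adjusted p = 1.19e-13), with Ccl20 from 14.6 ± 5.84 to 3903 ± 181 CPM. Stem genes fell in 5 of 8 with 1 that rose (adjusted p = 0.00131, and adjusted p = 0.0493 with an estimated correlation). Lgr5 went from 228 ± 8.50 to 6.48 ± 0.574 CPM (log2 fold change -5.07 ± 0.46, adjusted p = 2.68e-08). Smoc2, a secreted calcium-binding protein of stem cells, was at -3.04 ± 0.32. Ascl2, a stem cell transcription factor, was the member that rose (1.47 ± 0.48), a call lost without any 1 of the 4 plates (first and second day 0 plate, adjusted p = 0.0622 and 0.142; first and second day 3 plate, 0.0526 and 0.256, and 0.00971 to 0.711 over its alternatives). Of 12 enterocyte genes 8 rose and Fabp1 fell (8 rose and 2 fell adjusted over the list alone, adjusted p = 4.16e-06, and adjusted p = 0.0924 with an estimated correlation), for example Alpi from 253 ± 80.9 to 629 ± 28.6 CPM. With each cell weighted equally the calls of Alpi and Fabp1 were lost (adjusted p = 0.148, 6.77e-05 to 0.148 over its alternatives, and 0.144, 1.79e-07 to 0.144).

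The day 3 comparison of this arm called 1167 of 6499 tested genes, 650 up and 517 down. With each cell weighted equally it called 221, of which 76.5% were rises. It called 527 genes without the second day 3 plate, 651 without the first day 0 plate and 756 without the second; rises were 66.6% and 69.5% without the first or second day 3 plate. BMP targets rose in 5 of 6 (6 adjusted over the list alone, adjusted p = 5.3e-08), with Bmp2, itself a BMP ligand, at 5.88 ± 0.43 and Id2 at 4.02 ± 0.35. Carbohydrate absorption genes rose in 7 of 11 (8 adjusted over the list alone, adjusted p = 0.00131, and adjusted p = 0.0924 with an estimated correlation), for example Sis, the sucrase-isomaltase (3.09 ± 0.38). Dpp4, a brush border peptidase of this list, fell, a call lost without the second day 0 plate or either day 3 plate (adjusted p = 0.238, 0.212 and 0.0881, and 0.0226 to 0.546 over its alternatives). Immediate early genes fell in 8 of 10 (adjusted p = 1.1e-06, and adjusted p = 0.0997 with an estimated correlation), Jun by 3.63 ± 0.32. Goblet genes rose in 4 of 8 (5 adjusted over the list alone, adjusted p = 0.00647, and adjusted p = 0.358 with an estimated correlation), among them Zg16, a lectin of mucin granules, at least 211-fold, and Muc2, the main gel-forming mucin (4.03 ± 1.04). Without the second day 3 plate both calls were lost (adjusted p = 0.0522 for Zg16, 2.83e-09 to 0.141 over its alternatives, and 0.0553 for Muc2, 8.04e-06 to 0.521), and without the first day 0 plate that of Muc2 (adjusted p = 0.0534), which DESeq2 (0.155) and equal weights of cells (0.521) ended as well. Other large rises were H2-M2, at least 113-fold, Pglyrp2, a peptidoglycan hydrolase, at least 79.3-fold, and Rac2, a small GTPase, at least 71.8-fold. Rgcc was lower by a ratio of 49.8 (95% counting interval 13.6 to 415). Of 6 interferon genes Oasl2 rose (list adjusted p = 0.965), a call lost without the second day 0 or second day 3 plate (adjusted p = 0.0716 and 0.360, and 0.00352 to 0.402 over its alternatives). Of 16 cholesterol genes Msmo1 rose (0 adjusted over the list alone, list adjusted p = 0.206), a call lost without any 1 of the 4 plates (first and second day 0 plate, adjusted p = 0.0875 and 0.186; first and second day 3 plate, 0.0501 and 0.284, and 0.0179 to 0.284 over its alternatives).

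On day 6 of RANKL+CSRM617, M cell genes were above day 0 and stem and cell cycle genes below it. M cell genes rose in 6 of 7 (7 adjusted over the list alone, camera adjusted p = 3.98e-10; median 3.16), with Anxa5 at 5.57 ± 0.36, Serpinb1a at 3.20 ± 0.30 and Spib at least 65.1-fold higher. Lgr5 had no UMI on day 6 against 235 on day 0, at least 19.6-fold lower. With Lgr5, Olfm4 (-1.86 ± 0.37), Smoc2 (-3.35 ± 0.43) and Rgmb, a BMP coreceptor (-1.76 ± 0.54), 4 of 8 stem genes fell. The list had adjusted p = 0.00261 (adjusted p = 0.0592 with an estimated correlation). Cycling genes fell in 7 of 10 (9 adjusted over the list alone, adjusted p = 5.29e-07, and adjusted p = 0.119 with an estimated correlation), including the mitotic kinase Cdk1 (-3.18 ± 0.55) and Mki67 (-1.81 ± 0.53). Paneth genes rose in 5 of 7 (6 adjusted over the list alone, adjusted p = 0.00263, and adjusted p = 0.338 with an estimated correlation), with Ang4, an antimicrobial ribonuclease (5.08 ± 0.82), and Mptx2, a pentraxin of Paneth cells, was at least 133-fold higher. The call of Ang4 was lost with DESeq2 (adjusted p = 0.0664) and with each cell weighted equally (0.331, and 9.19e-11 to 0.331 over its alternatives). Leaving out a single plate ended some of these calls. Those of Olfm4 and Mptx2 were lost without the first and the second day 6 plate respectively (adjusted p = 0.0903, 3.6e-05 to 0.680 over its alternatives, and 0.194, 4e-07 to 0.349). That of Rgmb was lost without any 1 of the 4 plates (adjusted p = 0.0541 and 0.121 without the first and second day 0 plate, 0.261 and 0.212 without the first and second day 6 plate, and 0.0164 to 0.419 over its alternatives). That of Mki67 was lost without the second day 0 plate or either day 6 plate (adjusted p = 0.149, 0.218 and 0.176, and 0.00208 to 0.218 over its alternatives).

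The day 6 comparison called 488 genes, 296 up and 192 down. With each cell weighted equally it called 271, of which 45.0% were rises. Without the first or the second day 6 plate it called 214 and 236 genes, with 73.8% rises in the first case, and without the first day 0 plate 280. NF-kappaB genes rose in 8 of 12 (10 adjusted over the list alone, adjusted p = 2.79e-12), Ccl20 by 5.93 ± 0.44, and BMP targets in 4 of 6 (5 adjusted over the list alone, adjusted p = 2.44e-06), Bmp2 by 4.42 ± 0.59. Of 12 enterocyte genes 4 rose and 1 fell (5 and 3 adjusted over the list alone, adjusted p = 0.248), the rises including Krt20, an intermediate filament protein of mature cells (2.38 ± 0.36), and Apoa1, an apolipoprotein (2.37 ± 0.44). Alpi was at 0.17 ± 0.28 (adjusted p = 0.815) and Fabp1 fell by 5.44 ± 0.67. Called genes by day from 1 to 6 were 284, 635, 1167, 297, 500 and 488. Across the 6484 genes tested in both arms, the day 3 changes of the arms, which rest on separate day 0 plates, had a Pearson correlation across genes of 0.665 (Spearman 0.455), and 334 genes rose in both arms where independent lists give 76.7. On day 6 these values were 0.346 (Spearman 0.150), 151 and 54.9; genes are not independent replicates.

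Class shares in the RANKL+CSRM617 arm were clustered from its own table. Enterocyte-like cells were 32.3% ± 4.84 of a plate on day 0, 45.5% ± 2.90 on day 3 and 11.1% on day 6 (SD, n = 2). All 112 day 0 cells of this class were in a cluster led by Fabp1, and 82 of its 89 day 3 cells in another led by Reg3b, Ccl9 and Apoa1. At a higher cluster resolution, 1.6 against 1.0, 25 of these 89 cells were M cell-like and 64 enterocyte-like. Of the day 2 cells of the class, 38 of 50 were M cell-like at that resolution. On days 4, 5 and 6 these were 3 of 8, 4 of 7 and 5 of 12. In the RANKL arm 1 of 64 enterocyte-like cells on day 2 and 4 of 196 on day 3 were M cell-like there. Spib in the enterocyte-like cells of RANKL+CSRM617 on days 1 to 3 was at 579.5 ± 446 CPM (SD, n = 6). In M cell-like cells of the RANKL arm on the same days it was at 365 ± 186 (SD, n = 9). Stem-like cells were 19.8% ± 3.02 on day 1 and at or under 7.41% on all other days; this class was led by Olfm4, as in the RANKL table, and then by Edn1 and Thbs1, where Lgr5 and Rgcc followed in that table. A further cluster with Lgr5, Rgcc and Fgfbp1 in front, which had fewer markers than the 3 a name needs, held 44.9% of cells on day 0, 2.17% on day 1 and none of the cells of days 2 to 6. None of 5 classes followed the day over 14 plates (permutation test, lowest for enterocyte-like cells at r = -0.459, adjusted p = 0.493, and rho = -0.620, adjusted p = 0.106). No cluster of this table met the rule for M cell-like cells, so none of the 195 cells of day 3 had this name. The absence comes from the naming of clusters, and no counting limit applies to it. At the higher resolution M cell-like cells were 12.6% on day 3 and 4.61% on day 6. With both tables clustered together, without correction for differences between them, they were 56.4% and 33.3%, against 40.4% and 2.7% with RANKL. Clustered without the marker genes, an alternative chosen after seeing the data, the table had an M cell-like cluster of 249 cells led by Clec2h, Serpinb1a and Spib, which held 43.1% ± 10.1 of a plate on day 2, 19.1% ± 3.70 on day 3 and 25.97% ± 3.30 on day 6, against 46.4%, 48.6% and 2.59% with RANKL.

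The arms were compared over days 4 to 6, after the fall of the M cell-like share in the RANKL arm, to ask how the arm with the ONECUT2 inhibitor differed. Its plates of days 4, 5 and 6 held 67, 168 and 108 kept cells, against 197, 628 and 773 in the RANKL arm. Its day 0 plates held 345. On day 4 the UMI filter kept 69.1% of its wells, against 99.5% with RANKL. The bearing of these low numbers on the differences was not tested. Stem genes were lower with the inhibitor, and 7 of 8 passed (camera adjusted p = 2.36e-05; median log2 difference -1.70). Lgr5 was at 7.87 ± 12.4 CPM (SD, n = 6) against 393 ± 58.2 (SD, n = 9), lower by a ratio of 52.4 in summed counts (95% counting interval 26.5 to 121; 8 against 3106 UMIs). Olfm4 was at 1775 ± 1486 against 5862 ± 1894 and Smoc2 at 143 ± 98.8 against 432 ± 39.6. At day 0 none of the 8 passed and their median difference was 0.23. Wnt targets were lower in 9 of 13 (adjusted p = 0.00275; median -0.84). M cell genes were higher in 4 of 8 (5 adjusted over the list alone, adjusted p = 9.42e-05), with Spib at 161 ± 102 against 32.0 ± 12.6 CPM, Serpinb1a at 1378 ± 604 against 263 ± 66.2 and Anxa5 at 782 ± 207 against 231 ± 32.5. Sox8, another member of the list, had only 2 UMIs in each arm over these days. Its log2 difference in summed counts was 2.89 (95% counting interval -0.896 to 6.68). BMP targets were higher in 4 of 6 (adjusted p = 9.42e-05), Id1, an inhibitor of differentiation factors, at 191 ± 67.9 against 8.65 ± 3.33 CPM. Onecut2 itself was higher with the inhibitor (0.59 ± 0.11, adjusted p = 5.54e-05; 0.20 and adjusted p = 0.384 among cells with 3000 or more UMIs, 6.01e-07 to 0.384 over its alternatives). Its difference at day 0 was 0.16 ± 0.18 (adjusted p = 0.673). The call of Spib was lost without the first day 4 plate of the RANKL+CSRM617 arm (1.65, adjusted p = 0.133, and 3.04e-18 to 0.133 over its alternatives).

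**Figure D3:**
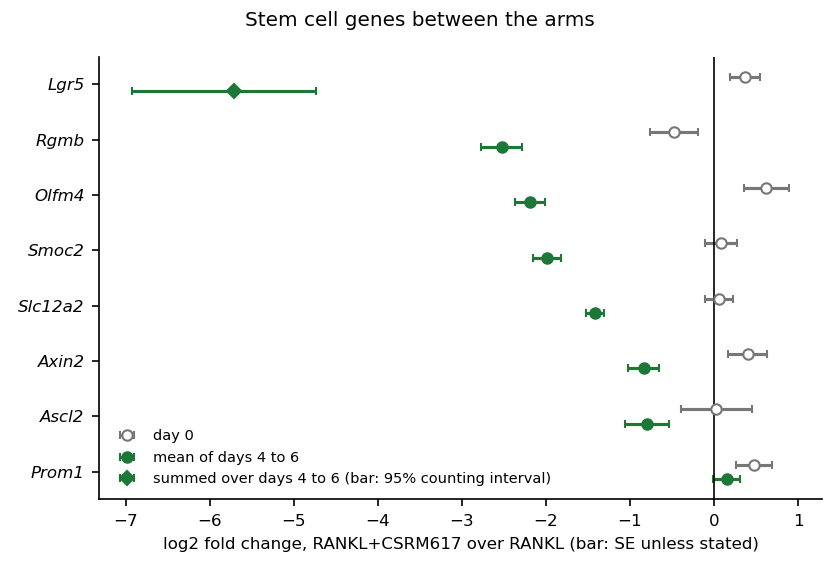
Log2 fold change between RANKL+CSRM617 and RANKL for the stem genes on the horizontal axis, at day 0 (open circles) and over days 4 to 6 (filled circles), with bars of 1 SE; Lgr5, which had no UMI on day 6 of RANKL+CSRM617, is drawn over days 4 to 6 as a diamond from summed counts with its 95% counting interval. At day 0 no gene of the list passed the test, and over days 4 to 6 Lgr5 was at -5.71 (-6.92 to -4.73).

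Over days 4 to 6 the arms differed in 1962 of 8766 genes, 761 higher and 1201 lower with the inhibitor. Higher calls were 16.7% of 1270 among cells with 3000 or more UMIs, 18.9% of 1207 with cells thinned to 2000 UMIs, 14.5% of 3817 with each cell weighted equally, and 25.7% of 1274 without the first day 4 plate of the RANKL+CSRM617 arm. The median of all genes lay at -0.12 and moved to -0.42, -0.34 and -0.47 under the first 3 of these settings, and the stem genes are to be read relative to that. Arm and plate series cannot be told apart here. At day 0, taken as the start of treatment in both arms, 861 genes already differed, 241 higher and 620 lower. With each cell weighted equally, 8.57% of 432 calls were higher. The day 0 count was 445 without the first and 530 without the second RANKL+CSRM617 plate of that day. Of the 1962 genes, 397 were called in the same direction at day 0, where independence gives 105.9. Cholesterol synthesis genes were higher in 11 of 17 over days 4 to 6 (adjusted p = 1.81e-06). NF-kappaB genes were higher in 5 of 12 (adjusted p = 0.00275, and adjusted p = 0.117 with an estimated correlation), Paneth genes in 4 of 8 (adjusted p = 0.00402, and adjusted p = 0.343 with an estimated correlation), and enterocyte genes in 1 of 13 (adjusted p = 0.407). That gene was Krt20, whose call was lost among cells with 3000 or more UMIs (0.26, adjusted p = 0.623) and with thinned cells (adjusted p = 0.153, and 1.35e-05 to 0.623 over its alternatives). Among other differences, Lgals3, a galectin of mature epithelium, was at 3.35 ± 0.36 and Scd1, a fatty acid desaturase, at 1.79 ± 0.15. The predicted genes Gm10800 and Gm10801 were higher at 5.07 ± 0.48 and 5.49 ± 0.46 and also at day 0 (4.07 ± 0.79 and 4.42 ± 0.74), where the call of Gm10800 was lost with each cell weighted equally (adjusted p = 0.0510, and 0.000231 to 0.0510 over its alternatives). Sdcbp, a scaffold protein, was lower by a ratio of 44.9 in summed counts (95% counting interval 23.6 to 98.4) and at -6.63 ± 0.43 on day 0. The enterocyte list was lower at day 0 in 9 of 13 (10 adjusted over the list alone, adjusted p = 2.05e-06, and adjusted p = 0.198 with an estimated correlation), and the interferon list in 8 of 11 (11 adjusted over the list alone, adjusted p = 1.12e-13).

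The changes from day 0 were then compared between the arms, which subtracts the day 0 difference. A list that differs only at day 0 therefore appears here with the opposite sign. The change in stem genes differed in 6 of 8, all toward a lower value with the inhibitor (camera adjusted p = 1.32e-08; median -1.76). Olfm4 differed by -2.81 ± 0.32, and Lgr5 passed as well (adjusted p = 3.69e-15), without a size here because it had no UMI on day 6 of RANKL+CSRM617. Wnt targets differed downward in 5 of 13 (7 adjusted over the list alone, adjusted p = 2.57e-05), with Axin2 at -1.24 ± 0.30. BMP targets differed upward in 4 of 6 (adjusted p = 7.83e-09), Id1 by 3.73 ± 0.36 and Bmp2 by 3.45 ± 0.66. Cholesterol synthesis genes differed upward in 12 of 17 (13 adjusted over the list alone, adjusted p = 2.89e-13). Enterocyte genes differed upward in 5 of 13 (adjusted p = 5.04e-07, and adjusted p = 0.062 with an estimated correlation), Krt20 by 3.23 ± 0.36 and Alpi by 2.35 ± 0.47. The enterocyte list was lower in the RANKL+CSRM617 arm at day 0, and only Krt20 was called over days 4 to 6. Its upward difference thus rests largely on the day 0 plates. M cell genes differed upward in 2 of 8 (2 upward and 1 downward adjusted over the list alone, adjusted p = 0.00102, and adjusted p = 0.062 with an estimated correlation), Serpinb1a by 2.90 ± 0.30 and Anxa5 by 2.16 ± 0.38. Interferon genes differed upward in 4 of 11 (6 adjusted over the list alone, adjusted p = 2.89e-13). In the RANKL arm their summed level was highest in the day 0 plates. In all 556 genes differed, 275 upward and 281 downward; upward calls were 25.3% of 202 among cells with 3000 or more UMIs, 28.1% of 228 with thinned cells and 34.1% with each cell weighted equally. The count was 357 without the first and 294 without the second day 0 plate of the RANKL+CSRM617 arm. Among the genes named, thinned cells ended the calls of Anxa5 (adjusted p = 0.0542, and 6.09e-05 to 0.0542 over its alternatives), Bmp2 (0.0518; 1.59e-05 to 0.351) and Axin2 (0.0792; 0.00156 to 0.136), and Axin2 also lost its call without the first day 0 plate of the RANKL+CSRM617 arm (0.0572). With thinned cells the differences of Anxa5, Bmp2 and Axin2 were 1.81, 3.31 and -1.30, close to their main values. The change in Onecut2 did not pass (0.44 ± 0.21, adjusted p = 0.232), but did with plates of 50 or more cells only (0.58, adjusted p = 0.0487, and 0.0487 to 0.817 over its alternatives).

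Of 5 classes compared between the arms over days 4 to 6, the stem-like share differed, at 3.61% with the inhibitor against 25.2% with RANKL (difference -21.6 points; exact permutation test within days, 1000 arrangements, p = 0.001, the smallest possible; adjusted p = 0.005). With plates of 50 or more cells only, an alternative chosen after seeing the data, the difference was -23.3 points and its adjusted p 0.05. At day 0 the difference was 1.55 points, between shares of 2.58% and 1.03%. Unnamed cells stayed outside the class, although at day 0 they had Lgr5 at 257.5 CPM with RANKL+CSRM617 and 301.8 CPM with RANKL. The small day 0 difference thus depends on the naming rule and does not show that the arms began with equal stem cells. The leading genes of the class also differed, with Edn1 and Thbs1 after Olfm4 in the RANKL+CSRM617 table and Lgr5 and Rgcc in the RANKL table. Cycling-like cells (1.28 points, exact p = 0.675), enterocyte-like cells (2.72 points, exact p = 0.291) and goblet- and Paneth-like cells (2.10 points, exact p = 0.281) did not pass, nor did tuft-like cells, chemosensory cells that were fewer by 2.74 points (exact p = 0.028, adjusted p = 0.07). Clustered jointly, the cycling-like difference was -13.2 points and the enterocyte-like one -6.92 (exact permutation test, adjusted p = 0.0117 and 0.0025). The cycling-like difference was -9.61 points at resolution 0.6 (same test, adjusted p = 0.025). Both directions thus depend on the clustering, and in the separate tables the cycling-like class leaves out unnamed clusters with Rrm2 and Uhrf1 in front. The enterocyte-like class of RANKL+CSRM617 also held cells of days 4 to 6 that were M cell-like at resolution 1.6. With both tables clustered together the stem-like difference was -32.9 points, and M cell-like cells were 15.4 points more frequent with the inhibitor (exact p = 0.003), while at the higher resolution of the separate tables their difference was -0.60 points (exact p = 0.658). Clustered without the marker genes it was 6.40 points (exact p = 0.165). The joint clustering had no correction for differences between the tables. Its clusters, and the differences between arms drawn from them, may therefore follow the table as well as the class. A joint M cell-like cluster of 452 cells had Krt20, a gene of the enterocyte list, among its leading genes.

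**Figure D4:**
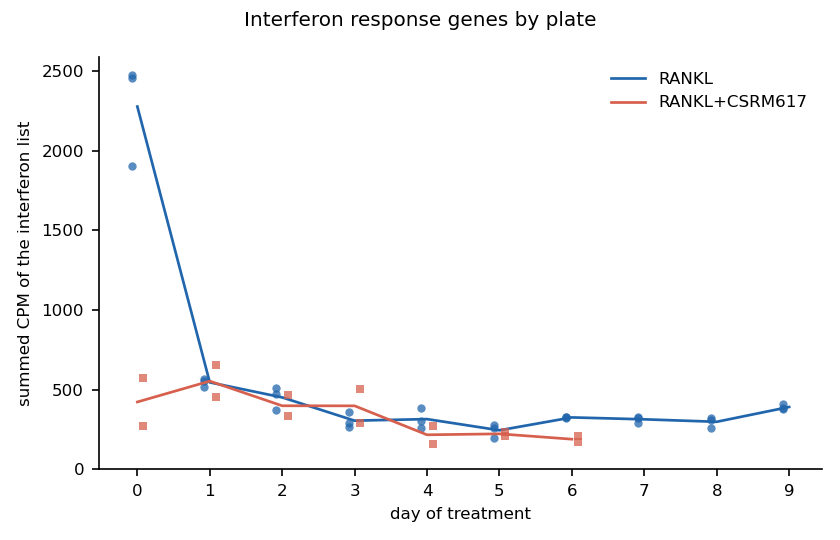
Summed normalised CPM of the interferon response list for each plate (points) and the mean of each day (lines) in both arms. The 3 RANKL day 0 plates lie at 1905 CPM or above, and no later RANKL plate exceeds 566.9 CPM.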

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

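All tests of explanations in this part were chosen after the results were seen; the comparison of changes and its lists were planned. The change from day 0 differed between the arms for 556 genes by the test of that difference itself. The median difference of the changes was -1.76 for the stem list, -0.99 for the Wnt targets, 2.49 for the BMP targets, 2.29 for the interferon list (2.15 with its 4 genes without counts on a day taken from summed counts, or from a floor of 3 counts) and 1.07 for the cholesterol synthesis list.

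Stem genes were lower with the inhibitor over days 4 to 6. Different counting of these genes in the tables would show at day 0, where their median difference was 0.226 against -1.70 later, and shallower cells would lift the difference once cells were thinned to 2000 UMIs, where it was -1.81 against -0.34 for all genes; the tables argue against both. The arms were separate plate series, 861 genes differed between them at day 0, and series that drifted apart after day 0 cannot be told apart from the inhibitor. An effect of ONECUT2 inhibition on stem cells, the biological reading the design names, stays open beside it. Over 60 splits of the 15 plates within this comparison the real one called the most genes, 1962 against at most 889 (1 of 60 as large). This argues against a chance assignment of plates. The real split also follows the plate series, so it cannot tell the inhibitor from the series.

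Interferon response genes were high in the RANKL day 0 plates, at 2278 ± 324 CPM summed (SD, n = 3) against 545 ± 26.9 on day 1 and 422 ± 215 in the day 0 plates of the other arm. A single aberrant plate is argued against by the lowest day 0 plate, 3.36 times the highest of 27 later RANKL plates. Immune cells among the sorted cells, as the whole cause, are argued against because 10 of 481 day 0 cells had a UMI of an immune marker, and among cells without one the median cell had 1292 CPM in the lowest day 0 plate and 352 in the highest later plate, a ratio of 3.67; immune markers were at 3.23 ± 3.18 CPM on day 0 and 3.06 later. Within the 3 clusters with 10 or more cells both on day 0 and later the ratio of day 0 to later days was 3.23, 2.65 and 1.38, the last in the Fabp1-led enterocyte-like cluster, which has Ifit1 among its leading genes. Whether the RANKL day 0 organoids were in another state than those of the other arm cannot be told apart from a difference between the plate series (median log2 difference at day 0, -3.55); in either case the fall of this list from day 0 may reflect the day 0 plates more than RANKL, and no biological explanation was tested.

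M cell genes (Spib, Serpinb1a and Anxa5 summed) were high on days 1 to 3 and low from day 4 in the RANKL arm. A single mislabelled or mixed plate is argued against by the gap between all 9 plates of days 1 to 3, at 1630 CPM or above, and all 18 plates of days 4 to 9, at 687.6 or below, a ratio of 2.37. A transient M cell-like state may be a biological reading, as a hypothesis found and tested on the same plates; a change of medium or passage between days 3 and 4 was not tested.

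For the changes of the RANKL arm the 6 plates of 2 days allow 10 splits, too few for a share under 0.05. In each case 1 of 10 splits, the real one, gave as many genes. The real split called 2043 genes on day 3 (highest other 3), 3828 on day 6 (highest other 144) and 3638 on day 9 (highest other 212).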

How the results depend on the processing

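The tests with plates of 50 or more cells, the plate tag, crossed numbers, without the most abundant gene and with clustering on non-marker genes were chosen only after the results were seen. Counts of called genes in the 3 RANKL comparisons stayed within 1.5 times under all alternatives run, with leave-one-out ranges of 1554 to 1934, 3115 to 3749 and 2923 to 3586 on days 3, 6 and 9. In the RANKL+CSRM617 arm day 3 gave 221 genes with each cell weighted equally and 527 to 825 leaving out a plate. Day 6 gave 200 among cells with 3000 or more UMIs, 226 with the plate tag as a factor, 271 with each cell weighted equally and 214 to 377 leaving out a plate. Between arms over days 4 to 6 the count was 1270 with 3000 or more UMIs, 1207 thinned, 3817 with each cell weighted equally and 1274 to 1949 leaving out a plate. At day 0 it was 475 thinned, 432 with each cell weighted equally and 445 to 818 leaving out a plate, the lowest being without the first RANKL+CSRM617 plate and 530 without the second. For the changes it was 202 with 3000 or more UMIs, 228 thinned, 1012 with plates of 50 or more cells and 294 to 601 leaving out a plate. Of the list tests 91 passed, 41 of them also with an estimated correlation, and 92 passed with the replicate number as a block. The cause of these differences was not tested.

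Replicate numbers do not pair the samples: deviations of equally numbered plates correlated at -0.09 to 0.14 with day 0 in the RANKL arm. With the replicate number as a block, day 0 of the arms gave 547 genes, and the other comparisons 2001, 3777, 3551, 1076, 453, 1361 and 499; Paneth and ER stress lists between arms were at adjusted p = 0.0648 and 0.127. In the RANKL+CSRM617 arm day 3 plates correlated at -0.18 with day 0 plates of the same number, and crossed numbers gave 1110 genes.

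Among class shares, RANKL had 5 to 6 classes related to the day leaving out a plate. RANKL+CSRM617 had 1 at resolution 0.6, clustered jointly or with 3000 or more UMIs, and 0 to 1 leaving out a plate (1 without either day 3 plate). Between arms, 3 classes differed at resolution 0.6 and clustered jointly, 2 with 3000 or more UMIs, 0 with plates of 50 or more cells, where few arrangements remain, and 1 to 2 leaving out a plate (2, tuft-like added, without the second RANKL day 4 or first day 6 plate). Directions that reversed were, as rho with the day, cycling-like in RANKL, 0.0262 jointly and 0.369 with 3000 or more UMIs. In RANKL+CSRM617 they were stem-like, 0.112 without marker genes; cycling-like, -0.346 at resolution 0.6, -0.0709 jointly and -0.0831 without either day 0 plate (-0.0831 to 0.277 leaving out a plate); and goblet- and Paneth-like, -0.0709 at resolution 1.6, -0.0532 jointly, -0.0609 without the first day 5 and -0.0997 without the first day 6 plate (-0.0997 to 0.202 leaving out a plate). Between arms they were, in points, cycling-like, -9.61 at resolution 0.6, -13.2 jointly, -0.731 with 3000 or more UMIs and -5.45 with plates of 50 or more cells; enterocyte-like, -6.92 jointly; and goblet- and Paneth-like, -0.425 at resolution 1.6. Among named genes, which kept direction and side in 2319 of 2414 values, Alpi on day 6 of RANKL+CSRM617 was at -0.047 with 3000 or more UMIs and -0.13 to 0.55 leaving out a plate, and Onecut2 between arms at day 0 at -0.0142 with plates of 50 or more cells. Of 467 alternative values over 17 class results, 433 kept direction and side of the threshold. In the RANKL+CSRM617 arm fewer plates and fewer UMIs limit small changes, and the part of each was not separated.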

Other observations

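The test of Onecut2 by class in this part was chosen after the results were seen. A cluster of RANKL cells that met no class rule was led by Edn1, Anxa3, Clu and Thbs1, which encode an endothelin, an annexin, the chaperone clusterin and a matrix glycoprotein. It held 0.624% of cells on day 0, 16.2% on day 4, 9.08% on day 5, 36.1% on day 6, 6.74% on day 7 and 35% on day 9. In the RANKL+CSRM617 table, Edn1 and Thbs1 stood beside Olfm4 among the leading genes of the stem-like class, which was 19.8% of a day 1 plate. A further unnamed RANKL cluster, led by Gm1123, Fos, Cldn2 and Mt2, held 43.0% of day 0 cells and none of days 1 to 4. In the RANKL+CSRM617 table an unnamed cluster led by Ppp1r9a, Itga1 and Sema5a held 48.8% of cells on day 5 and 44.4% on day 6, and another, led by Clec2h, Gsta4 and Guca2a, held 37.1% on day 2 and 22.2% on day 6. None of these shares was tested.

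Tuft-like cells, the chemosensory class, were not seen on day 0 of the RANKL arm (0 of 481 cells, which allows up to 0.624%) and were 3.47% ± 0.662 of a plate on day 3, 5.72% ± 3.22 on day 4 and 1.87% ± 0.465 on day 9 (SD, n = 3). Their share rose within days 1 to 3 (r = 0.890, exact permutation test adjusted over 19 relations, adjusted p = 0.0113; rho = 0.949, adjusted p = 0.00994; r = 0.826 without the 2 farthest plates). It fell within days 4 to 9 (permutation test, r = -0.529, adjusted p = 0.0352; rho = -0.618, adjusted p = 0.0264; r = -0.422 without 2 plates). Enteroendocrine-like cells, the hormone-secreting class, were 0.728% on day 0, 2.43% on day 2, 0.278% on day 4 and 7.12% ± 2.44 on day 8. They rose within days 4 to 9 (permutation test, r = 0.662, adjusted p = 0.0123; rho = 0.706, adjusted p = 0.00994; r = 0.565 without 2 plates) and had no tested trend within days 1 to 3 (r = -0.235, adjusted p = 0.576; rho = -0.264, adjusted p = 0.628; r = -0.35 without 2 plates). On day 3, Trpm5, the cation channel of taste transduction, was at least 10.9-fold and Pou2f3, the transcription factor that tuft cells need, at least 9.52-fold above day 0.

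Some genes were nearly absent from the RANKL+CSRM617 plates of days 4 to 6. Between arms over these days, Zfp445 was lower with the inhibitor by a ratio of 81.7 (95% counting interval 27.9 to 397; 3 against 1817 UMIs), and at day 0 by at least 51.2-fold. Csnk1d was lower by a ratio of 58.9 (16.3 to 487) over days 4 to 6.

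Onecut2 RNA may be linked to the M cell-like state. Under this hypothesis Onecut2 would be higher in M cell-like cells than in the other cells of the same plate. On the 9 RANKL plates of days 1 to 3 the mean log2 ratio was 0.423 (1144 ± 155 against 890 ± 300 CPM; SD, n = 9), higher on 7 of 9 plates (exact sign-flip test, p = 0.0312, where the smallest possible is 0.00391), which is consistent with it. Enterocyte-like cells of the same days were higher still, at 1329 ± 433 CPM, against 715 ± 118 in cycling-like cells, so the level does not single out M cell-like cells. Tnfrsf11a was at 271 ± 31.0 against 221 ± 27.9 CPM, higher on all 9 plates (mean log2 ratio 0.29, exact sign-flip p = 0.00391). No test here separates the expression of Onecut2 from its activity.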
